A study of Mus musculus with 6 samples.

How the data were processed

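Limbal tissue of wild-type mice was sequenced from poly(A)-selected RNA in 6 samples, 3 from mice given subconjunctival L-733,060 on days 0 and 3 and 3 from controls given sterile water. Per the submitters' processing notes, reads passed through bcl2fastq, HISAT2 2.1.0 and HTSeq 0.11.2 with the mouse genome mm10; the settings, the strand mode of the counting and the annotation release are not given in the sources used here. The deposited values are a read count per gene and sample, as whole numbers. The authors also give TPM per gene and sample. The TPM values equal count divided by the deposited gene length (other), rescaled per sample, with a largest difference of 4.96e-06. Of 39089 genes in the table, 39063 have the position of the same symbol in the RefSeq annotation of GRCm38.p6. Each sample has its own column, and no per-sample column was left unused.

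Total counts were 21870713, 22142129 and 23541791 in controls 1 to 3, and 20780561, 18708288 and 21230942 in L-733,060 samples 1 to 3. At these depths 3 counts in a sample correspond to 0.128 to 0.161 CPM, and lower values are near absence. The 10 most abundant genes took 11.95 to 13.03% of the counts. Between samples of a group the chi-square per degree of freedom was 15.25 to 39.31 for genes with at least 20 counts, and between groups 182.5 to 271.4, so samples of a group varied more than counting error alone. No molecular identifiers are described, so PCR copies count as reads.

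Counts were analysed in R 4.3.3. Genes were kept by edgeR 4.0.16 filterByExpr (minimum count 10, minimum total 15), which left 15712 genes, 14010 of them protein coding, and removed 23377. Libraries were scaled by TMM, and a quasi-likelihood model compared L-733,060 with control in a two-sided F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are fitted log2 values, with a standard error of the absolute log2 value divided by the square root of F. The common biological coefficient of variation was 0.157. Levels are normalised CPM as mean ± SD of 3 samples. Where a group had no counts, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts, and for the untested Tac1, the ratio has an exact 95% interval that covers counting error only. An adjusted p in the report is from this edgeR test unless camera is named.

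Gene lists were tested with camera of limma 3.58.1 on log-CPM, with a preset correlation of 0.01, for lists with at least 5 tested members and adjusted over those lists. Of 31 lists, 28 were tested and 12 passed, 8 higher and 4 lower. With a correlation estimated per list none passed in camera, and 5 had an unadjusted p under 0.05, while fry of the same package passed 21. Camera asks whether a list changed more than the other genes, and fry whether it changed, without regard to other genes. As 41.3% of the tested genes passed the threshold, a fry call does not set a list apart from the other genes. For each list, members past the threshold were counted with adjustment over all genes and over the list alone.

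The comparison, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Tac1 and Tacr1, and the 8 largest rises and 8 largest falls among genes past the threshold with mean log-CPM above 0, no overlap of the groups and an established name. It also names up to 4 members of smallest p of each list that passed or had at least 3 members past the threshold, and up to 2 of other lists on the study's subject. Chosen after values were seen were the genes that the report or the closing section names beyond that rule. They include further members of the lists (such as Krt15, Trp63, Pax6, Krt13, Muc5ac, Mki67, S100a9, Tnf, Akt1, Arntl, Krt1, Ivl, Ddx3y and Uty), genes outside them (A830036E02Rik, Pf4, Sox2 and lacrimal acinar genes) and 8 gene families: keratins, small proline-rich proteins, chemokine ligands, matrix metalloproteinases, glycolysis, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation and cholesterol synthesis.

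The method was tested on simulated data, with 200 genes changed in counts resembling these. At a simulated absolute log2 change of 0.5, 16.2% of 68 changed genes were called, at 1, 63.5% of 63, and at 2, 96.9% of 64. Of 115 calls, 2 were false (1.74%). A shifted list was called, and none of 27 unshifted lists was called by camera. The simulated genes varied independently of each other, so this does not test lists with correlated members. The list of neutrophils and acute inflammation, for example, had an estimated correlation of 0.721. In this simulation, changes of under a doubling were therefore often missed at 3 samples per group. It changed only 200 genes, whereas 6496 of 15712 were called in the comparison itself. The adjustment is less strict when more genes change, so these rates do not give the power of that comparison.

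Alternatives were DESeq2 1.42.0 size factors in the same fit, the DESeq2 Wald test, limma-voom without and with sample quality weights, no filter on low counts, a filter of at least 1 CPM in 3 samples, limma-trend on log2 TPM with pseudocounts of 1 and 0.1, and scaling without the 50 most abundant genes. Further ones were a threshold of at least 1 on the absolute log2 fold change, an adjusted p under 0.1, a block on replicate number, and each sample left out in turn. Lists were also tested with fry, with an estimated correlation and on ranks. The labels do not state that equal replicate numbers in the groups mark a shared litter or day, so the main comparison is unpaired. The 13 mitochondrially encoded genes listed as a quality measure were not analysed here. Results of some single genes are not reported here.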

Results

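The corneal limbus, the rim between cornea and conjunctiva that holds the stem cells of the corneal epithelium, was profiled by RNA sequencing in 6 mouse samples. In 3 samples the mice had been given L-733,060, an antagonist of the NK1 receptor for the neuropeptide substance P, under the conjunctiva on days 0 and 3, and in the 3 control samples sterile water. The limbus was taken after a week. The labels do not give the days of the control injections, so a difference in injection schedule between the groups cannot be ruled out. Total counts per sample ran from 18708288 in L-733,060 sample 2 to 23541791 in control sample 3. The labels do not say that samples of a group come from separate mice, so the p-values measure only the spread between these samples, which may be technical.

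The comparison asks how blocking the substance P receptor changes gene expression in the limbus, with limbal stem cell properties and the PI3K-AKT pathway as the subjects that the study's title names. In the limbus given L-733,060, 10 of 20 genes of corneal epithelial differentiation fell and 5 rose, with Krt12 12.0-fold and Aldh3a1 12.8-fold lower. Of the wound and stress keratins, Krt17 rose by log2 4.89, Krt16 by 5.13 and Krt6a by 0.70, while Krt6b did not pass (log2 fold change 0.24, edgeR adjusted p = 0.183). All 35 tested cell cycle genes rose. Of the tested genes, 18 of 19 for neutrophils and acute inflammation, 16 of 21 for macrophages and 11 of 15 for conjunctival epithelium rose, while 3 conjunctival genes and 12 of 18 clock genes fell. Of the 12 list calls made by camera, 0 were kept with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 21 lists. Of 38 core PI3K-AKT genes, 22 did not pass the threshold, the kinases Akt1 and Akt2 among them, beside 9216 of all 15712 tested genes. These are RNA levels, and the activity of the pathway was not measured here. Across 15712 tested genes, 3367 rose and 3129 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1684 at least doubled and 1305 at least halved. The groups did not overlap in 52% of the tested genes, where chance gives 10%, and the first principal component, with 79.6% of the variance, separated the groups.

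Transcripts of the targeted system were scarce. Tacr1, which encodes the NK1 receptor (chromosome 6, 82402003 to 82560104, plus strand, mm10), measured 2.55 ± 0.778 CPM in controls and 1.91 ± 0.609 CPM with L-733,060 (mean ± SD, n = 3 each). Its log2 fold change of -0.43 (SE 0.33) did not pass edgeR's quasi-likelihood test (adjusted p = 0.323). Tac1, the precursor of substance P, had 13 counts over the 3 controls and 4 over the 3 L-733,060 samples. That ratio of 0.330 (0.497 without L-733,060 1) has a 95% counting interval of 0.0783 to 1.07, so no difference was detectable at this depth. The blocking of the receptor itself is not visible in RNA levels, and the antagonist's action was not measured here.

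The named genes with the largest rises included cornified envelope proteins and chemokines. Ppbp, a chemokine that attracts neutrophils (chromosome 5, 90768518 to 90770063, plus strand), rose from 3.26 ± 0.606 to 3125 ± 1248 CPM (mean ± SD, n = 3; log2 fold change 9.90, SE 0.36; edgeR adjusted p = 1.65e-08). Esp6, of a family of exocrine gland peptides, rose from 0.242 ± 0.0353 to 105.6 ± 29.3 CPM (edgeR adjusted p = 1.65e-08). Sprr2f had 1 count over the controls against 1363, a ratio of 1461 with a 95% counting interval of 261.8 to 57750. Ratios for the other near-absent genes were 939.5 for Sprr3 (interval 259.7 to 7764), 915.4 for Sprr1b (163.9 to 36200) and 518.8 for the chemokine Cxcl3 (143.2 to 4290). Pappa, a protease that releases insulin-like growth factors, and Tnfsf11, the RANK ligand, had no counts in controls. They were at least 130.1-fold and at least 53.95-fold higher, against a floor of 3 counts over the group. Single samples moved these values. Without L-733,060 1 the ratios were 724.7 (Sprr2f), 504.4 (Sprr3), 456.7 (Sprr1b) and 131.5 (Cxcl3), and the bounds 78.5-fold (Pappa) and 33.9-fold (Tnfsf11). Without control 3 they were 945.6, 608.1, 592.5 and 335.8, and 84.2-fold and 34.9-fold. No control counts were left for Sprr2f without control 2 (at least 330.6-fold) or for Sprr1b and Cxcl3 without control 1 (at least 205.6-fold and 233.1-fold). Members of the Sprr2 family are near-identical in sequence, so the split of reads among them is uncertain.

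The largest falls were in genes of other kinds. Lypd2, a small Ly6-type protein (chromosome 15, 74732246 to 74734795, minus strand), fell from 2538 ± 486 to 44.2 ± 22.6 CPM (log2 fold change -5.84, SE 0.35; edgeR adjusted p = 2.67e-07). Gldc, of the glycine cleavage system, fell from 45.9 ± 7.01 to 0.699 ± 0.241 CPM (log2 fold change -6.03, SE 0.23; edgeR adjusted p = 2.27e-08). The opioid precursor Pdyn fell by 6.23 on the log2 scale, the protease gene Adamts18 by 6.15, the channel family member Ano4 by 4.98 and the cytochrome Cyp2b19 by 4.90 (edgeR adjusted p at most 1.66e-06). Dlx3, a transcription factor of stratified epithelia, had 166 counts in controls and 2 with L-733,060, a ratio of 0.0129 (95% counting interval 0.00155 to 0.0474). For Spink7, a protease inhibitor, the counts were 122 and 3, a ratio of 0.0264 (0.00536 to 0.0789; 0.0138 without L-733,060 3). Of the 5 counts of Adamts18 with L-733,060, most were in sample 1 (0.144 CPM, against 0.0535 and 0.0447 CPM).

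**Figure D1:**
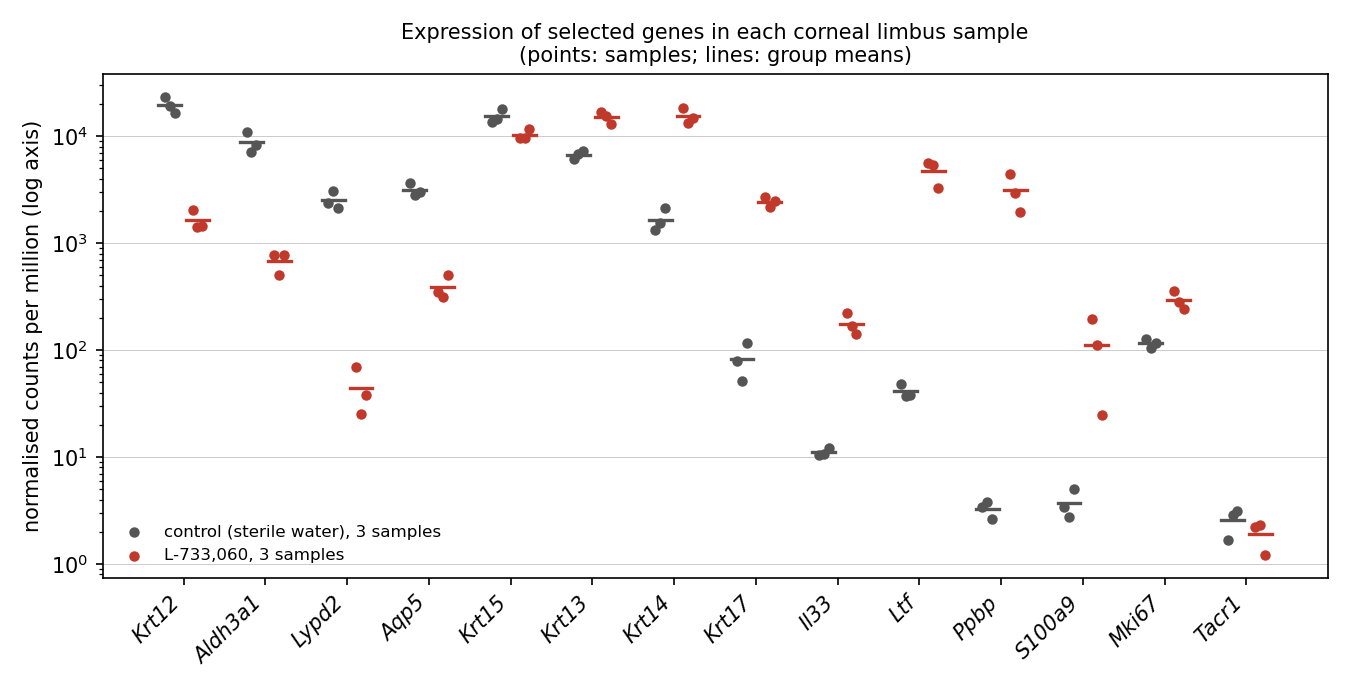
Normalised CPM on a log axis for 14 genes, with 1 point per sample (grey, 3 controls; red, 3 L-733,060 samples) and a line at each group mean. Krt12 has means of 19688 and 1646 CPM, Krt14 of 1665 and 15440.1 CPM and Ppbp of 3.26 and 3125 CPM, with no overlap of the groups, whereas the Tacr1 groups overlap.

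More genes of corneal epithelial differentiation fell than rose. Krt12, the keratin of differentiated corneal epithelium (chromosome 11, 99415664 to 99422593, minus strand), fell from 19688 ± 3356 to 1646 ± 362 CPM (mean ± SD, n = 3; log2 fold change -3.58, SE 0.20; edgeR adjusted p = 2.00e-07). The corneal crystallin enzymes Aldh3a1 and Aldh1a1 fell by 3.68 and by 3.49 on the log2 scale, and the uroplakin Upk3b fell by 4.66 (edgeR adjusted p at most 2.75e-07). Of the 20 tested members, 10 fell, 5 rose and 5 did not pass the threshold, and the counts adjusted over the list alone were 10 lower and 5 higher. The members that rose, singled out after their values were seen, were the secreted chaperone Clu (log2 fold change 2.18), Aldh1a3 (1.23), Gja1 (0.51), and the enzymes of sugar metabolism Ldhb (1.27) and Pgk1 (1.52). The list's median was -0.68. Its fall passed camera with a preset correlation (adjusted p = 1.36e-06), but not on ranks (adjusted p = 0.149), and had an adjusted p = 0.213 with an estimated correlation. A830036E02Rik, named after its values were seen, overlaps Krt12 on the opposite strand and had a log2 fold change of -3.75, and because the strand setting of the counting is not given in the sources used here, reads of the pair cannot be told apart.

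Limbal and basal epithelial markers moved both ways. Krt14, a keratin of basal epithelial cells (chromosome 11, 100203162 to 100207510, minus strand), rose from 1665 ± 410 to 15440.1 ± 2547 CPM (log2 fold change 3.21, SE 0.21; edgeR adjusted p = 4.51e-07). Ifitm3 and Cd63, reported in limbal progenitors, rose by log2 2.20 and 1.49, while Lrig1, a brake on growth factor receptors, fell by 1.37 (edgeR adjusted p at most 2.58e-05). In all, 9 of 22 tested members rose and 6 fell, with the same 9 and 6 adjusted over the list alone. The list as a whole was not past the threshold (camera adjusted p = 0.0625, and adjusted p = 0.391 with an estimated correlation), but passed fry (adjusted p = 0.0103). Without control 1, control 3, L-733,060 1 or L-733,060 2 it did pass, at adjusted p-values of 0.0341, 0.0376, 0.0316 and 0.0287. Genes named after their values were seen include the progenitor factor Trp63, at 204 ± 18.4 CPM in controls and 228 ± 14.7 CPM with L-733,060 (edgeR adjusted p = 0.297). Gpha2, a marker of quiescent limbal stem cells, rose by log2 0.90, and the transporter Abcg2 fell by 0.96 and Krt5 by 0.86 (edgeR adjusted p at most 0.00172). Krt15 (log2 fold change -0.57) and the eye-field factor Pax6 (-0.45) passed with all samples, but without L-733,060 1 their adjusted p-values were 0.0507 and 0.0573 and 3 members of the list fell. Without control 3 the adjusted p of Krt15 was 0.0718.

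Keratins and mucins of the conjunctiva rose, with exceptions. Krt7, Krt4 and the membrane mucin Muc1 rose by log2 1.68 (SE 0.13), 1.53 (SE 0.14) and 1.49 (SE 0.15), with edgeR adjusted p-values of at most 1.11e-05. Krt13, named after its values were seen, rose from 6742 ± 578 to 15168 ± 2017 CPM (log2 fold change 1.17, SE 0.15; edgeR adjusted p = 9.05e-05), as did the goblet cell mucin Muc5ac (log2 fold change 4.40, SE 0.67), which in controls measured 0.925 CPM in sample 1 and at most 0.0855 CPM in the others. In this list of conjunctival epithelium and goblet cells, 11 of 15 tested members rose and 3 fell, or 11 and 4 adjusted over the list alone. Those that fell were the water channel Aqp5 (3148 ± 449 to 389 ± 99.8 CPM, log2 fold change -3.02), the claudin Cldn10 (-1.62) and the mucin Muc4 (-0.46). Muc4 lost its call without control 1 (adjusted p = 0.0727), control 3 (0.0632) or L-733,060 1 (0.115). The list had a median of 1.17, also with its 2 members without control counts set at their lower bounds, and passed camera (adjusted p = 0.00680, but adjusted p = 0.213 with an estimated correlation).

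Genes of wounded and cornifying epithelium showed some of the largest rises. Krt17 (82.5 ± 32.5 to 2439 ± 248 CPM) and Krt16 (36.2 ± 14.1 to 1269 ± 360 CPM), keratins induced in activated keratinocytes, rose by log2 4.89 (SE 0.27) and 5.13 (SE 0.29), with edgeR adjusted p-values of 1.70e-07 and 2.15e-07. The alarmin Il33 rose by log2 3.99 (SE 0.18; edgeR adjusted p = 6.53e-08) and the collagenase Mmp13 by 5.87 (SE 0.32; edgeR adjusted p = 1.49e-07). Of 18 tested wound and stress genes, 15 rose and none fell, also when adjusted over the list alone (median 1.62; camera adjusted p = 8.46e-17, adjusted p = 0.213 with an estimated correlation). Of 15 tested genes of epidermal keratinization, 10 rose and 3 fell, or 10 and 4 adjusted over the list alone (median 2.30; camera adjusted p = 0.00279, adjusted p = 0.467 with an estimated correlation). Sprr1a rose by log2 5.71 and Dmkn by 5.17 (4.37 without L-733,060 1; edgeR adjusted p at most 1.64e-05), and Sprr2a1 had 1 count in controls against 346, a ratio of 370.9 (95% counting interval 66.1 to 14690; at least 80.0-fold without control 3, which held that count). The protease genes Asprv1 (log2 fold change -0.55) and Casp14 (-1.53), which act late in epidermal differentiation, and Krt77 (-1.38) fell. The epidermal keratin Krt1 and involucrin, Ivl, had log2 fold changes of -0.57 and -0.02, not past the threshold.

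Proliferation genes rose without exception, 35 of 35, and likewise adjusted over the list alone. With each sample left out in turn, 30 (without control 3) to 34 (without control 2) passed as higher and none as lower. The mitotic genes Tpx2, Cenpe and Bub1 rose by log2 1.47 (SE 0.14), 1.75 (SE 0.18) and 1.69 (SE 0.17), and Mcm4, of the replicative helicase, by 1.34 (SE 0.14), with edgeR adjusted p-values of at most 2.03e-05. Mki67, named after its values were seen, rose from 117 ± 10.9 to 296 ± 59.3 CPM (log2 fold change 1.34, SE 0.15; edgeR adjusted p = 3.39e-05). The list had a median of 1.17 and a camera adjusted p = 5.43e-15, but adjusted p = 0.248 with an estimated correlation. In the same samples the G1 cyclin Ccnd1 fell from 273 ± 21.8 to 140.0 ± 28.0 CPM (log2 fold change -0.97, SE 0.15; edgeR adjusted p = 3.06e-04).

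**Figure D2:**
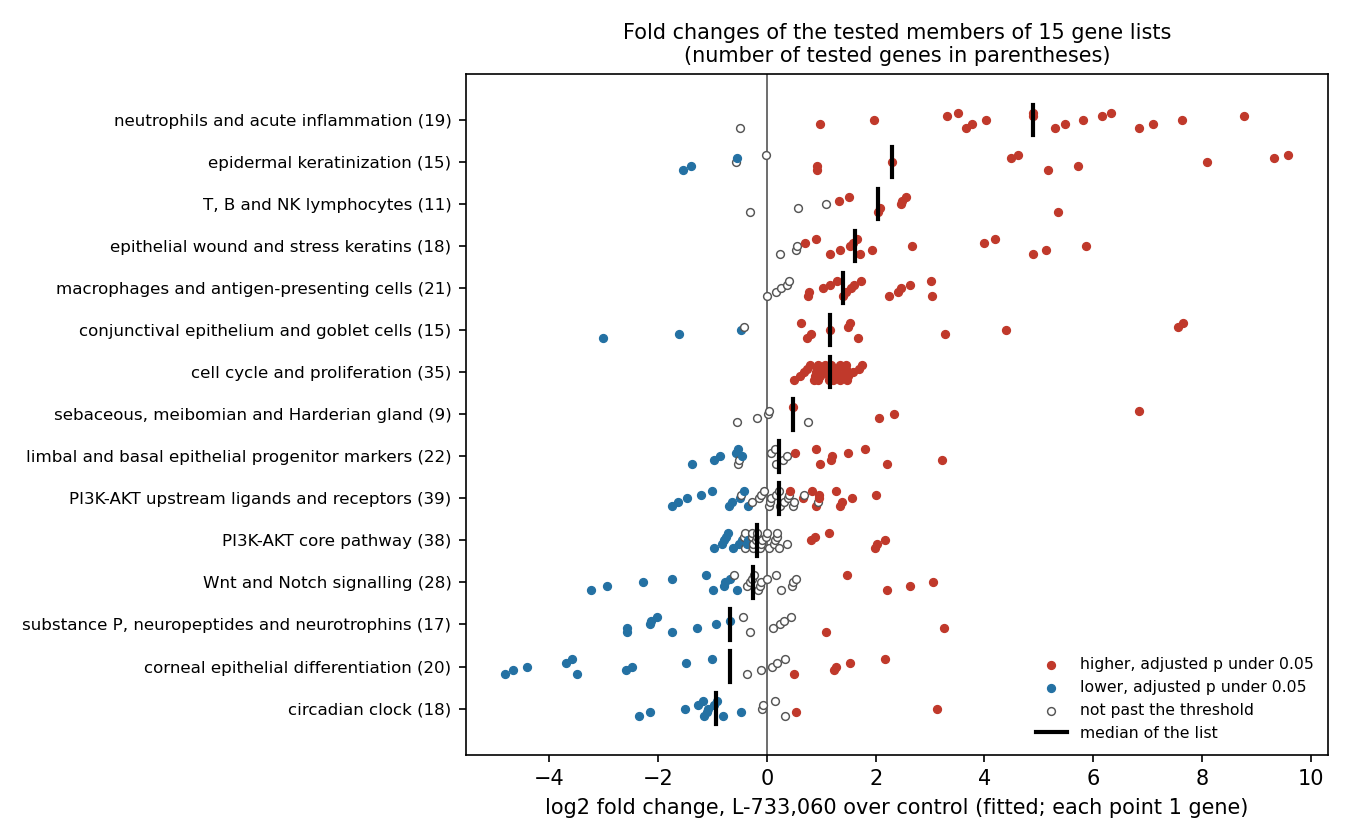
Fitted log2 fold changes (L-733,060 over control, 1 point per tested gene) of the members of 15 gene lists, which are those that passed the list test and those on the study's subject. Red and blue points passed an adjusted p of 0.05, open points did not, and the black bar is the median, from -0.94 for the circadian clock to 4.90 for neutrophils and acute inflammation.

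Markers of leukocytes and acute inflammation rose. Of 19 tested genes of neutrophils and acute inflammation, 18 rose and none fell, also adjusted over the list alone (median 4.90; camera adjusted p = 9.50e-14, adjusted p = 0.288 with an estimated correlation). The gelatinase Mmp9 rose from 0.122 ± 0.0572 to 10.2 ± 2.37 CPM, and the chemokines Ccl7 (7 counts in controls, most in control 1) and Ccl2 rose by log2 5.29 and 3.78 (edgeR adjusted p at most 2.89e-06). The neutrophil protein genes S100a8 and S100a9 rose by log2 5.82 (SE 0.53) and 4.89 (SE 0.61; 4.18 without L-733,060 1), and S100a8 ranged from 14.3 to 55.3 CPM among the L-733,060 samples. Tnf was the member that did not pass (log2 fold change -0.49, edgeR adjusted p = 0.249). Of 21 macrophage and antigen-presenting cell genes, 16 rose and none fell, or 17 and none adjusted over the list alone (median 1.41; camera adjusted p = 1.69e-10, adjusted p = 0.288 with an estimated correlation). Lysozyme, Lyz2, rose from 20.5 ± 3.84 to 169 ± 18.9 CPM, the mannose receptor Mrc1 by log2 3.02, Cd14 by 2.64 and Fcer1g by 2.25 (edgeR adjusted p at most 1.25e-05). Among 11 lymphocyte genes 8 rose and none fell, or 9 and none adjusted over the list alone (median 2.05; camera adjusted p = 0.00926, adjusted p = 0.213 with an estimated correlation). Levels were low: Cd8a reached 1.19 ± 0.477 CPM, Cd3g 0.956 ± 0.309 CPM and Gzmb 0.616 ± 0.117 CPM. Cd3d had 1 count in controls and 52 with L-733,060, a ratio of 55.7 (95% counting interval 9.57 to 2243; 36.1 without control 3, at least 12.6-fold without control 2, which held that count).

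Mast cell and interferon genes were not called as lists by camera, though mast cell genes passed fry (adjusted p = 0.0123). Of 6 mast cell genes, 2 rose and 3 fell, also adjusted over the list alone (median -0.68, -1.16 without control 3, -1.19 without L-733,060 2 and -1.25 without L-733,060 3; camera adjusted p = 0.243). The protease Cpa3, Kit and Hpgds fell by 3.79, 1.07 and 1.30 on the log2 scale, and the histamine-forming enzyme Hdc rose by 4.56 (3.73 without L-733,060 1; edgeR adjusted p at most 0.00145). Without control 1, control 3, L-733,060 1 or L-733,060 2, 1 mast cell gene rose in place of 2. Of 26 interferon response genes, 2 rose and 2 fell, or 2 and 1 adjusted over the list alone (median 0.09; camera adjusted p = 0.981). That median was 0.06 without control 1, 0.21 without control 2, 0.38 without L-733,060 1, -0.22 without L-733,060 2 and 0.14 without L-733,060 3. Zbp1 and Cxcl10 rose by log2 1.29 and 2.77 (Cxcl10 3.47 without control 3), Irf7 fell by 0.67 and Oas3 by 0.88 (log2 fold change -0.55 without L-733,060 1). Single libraries decided these counts: without L-733,060 1 they were 7 and 2, without L-733,060 2 they were 2 and 5, without L-733,060 3 they were 6 and 3, and without control 3 they were 2 and 1. Oas3 lost its call without control 1 (adjusted p = 0.0957) or control 3 (0.0621).

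Genes of neuropeptides and neurotrophins fell on balance. Ntrk2, the receptor of brain-derived neurotrophic factor, fell from 16.7 ± 2.54 to 2.82 ± 0.336 CPM (log2 fold change -2.56, SE 0.19; edgeR adjusted p = 1.61e-06). The growth factor Ntf3 fell by 1.74 on the log2 scale, the receptor Ret by 2.02 and the opioid precursor Penk by 1.29 (edgeR adjusted p at most 2.19e-04). Of 17 tested members, 9 fell and 2 rose, likewise adjusted over the list alone (median -0.68, and -0.43 without control 3; camera adjusted p = 0.00551, adjusted p = 0.311 with an estimated correlation). Vipr1, a receptor of vasoactive intestinal peptide singled out after its values were seen, rose by log2 1.08. Schwann cell and nerve genes went both ways: of 16 tested, 4 rose and 6 fell, the same adjusted over the list alone, with a median of -0.25 (-0.16 without control 3, -0.40 without L-733,060 3), a mean of 0.04, a test direction down and a camera adjusted p = 0.618. The neurofilament Nefl fell by 1.68 and the myelin gene Pmp22 by 0.80 on the log2 scale, and Cnp and Gap43 rose by 0.89 and 1.11 (edgeR adjusted p at most 0.00333). Without L-733,060 1, 3 of these nerve genes rose and 3 fell.

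RNA of core genes of the PI3K-AKT pathway went both ways, and the list test camera did not call them. The activity of the pathway was not measured. Of 38 tested core genes, 6 rose, 10 fell and 22 did not pass, and 6 and 10 were also the counts adjusted over the list alone. The median log2 fold change was -0.17, the mean 0.02 and the test's direction down (camera adjusted p = 0.426, adjusted p = 0.616 with an estimated correlation), whereas the list passed fry (adjusted p = 0.0412). The members with the smallest p were the phosphatases Inpp5d (1.24 ± 0.328 to 4.97 ± 1.27 CPM; log2 fold change 2.00, SE 0.29) and Inpp4b (2.17, SE 0.33), which rose, Ccnd1, which fell, and the translation repressor Eif4ebp1 (0.88, SE 0.14), which rose (edgeR adjusted p at most 3.73e-04). Inpp5d is also a gene of blood cells, whose markers rose in the same samples. Foxo3, a transcription factor that AKT restrains, fell by 0.72 on the log2 scale, and Foxo1 and Foxo4 fell by 0.75 and 0.83 (edgeR adjusted p at most 6.61e-04). Genes singled out after their values were seen had log2 fold changes of 0.04 (Akt1), 0.19 (Pik3ca), -0.28 (Akt2), -0.26 (Pik3r1) and -0.39 (Mtor), with edgeR adjusted p-values of 0.0688 to 0.844. Akt2 passed without L-733,060 3 (adjusted p = 0.0239), as did Mtor (0.0121), which also passed without control 2 (0.0410), and Mtor overlaps Angptl7 on the opposite strand. Of 39 genes for ligands and receptors upstream of the pathway, 11 rose and 10 fell, the same adjusted over the list alone (median 0.23, and 0.14 without L-733,060 2 or L-733,060 3; camera adjusted p = 0.618, adjusted p = 0.708 with an estimated correlation; fry adjusted p = 0.0442). Vegfa, Igf1, Areg and the receptor Fgfr3 rose by log2 1.56, 1.26, 1.35 and 0.96 (edgeR adjusted p at most 1.78e-04).

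Stromal and matrix genes went both ways. The stromal proteoglycan genes Kera, Dcn and Lum fell, Kera from 175 ± 25.9 to 25.4 ± 7.76 CPM, Dcn by 2.02 and Lum by 1.25 on the log2 scale, as did Angptl7 by 3.26, and the fibrillar collagen Col3a1 rose from 82.4 ± 26.8 to 636 ± 80.6 CPM (edgeR adjusted p at most 9.80e-04). Of 24 keratocyte and fibroblast genes, 11 rose and 8 fell, or 11 and 11 adjusted over the list alone (median -0.22, -0.06 without control 3 and -0.10 without L-733,060 2; camera adjusted p = 0.680). Of 34 basement membrane and adhesion genes, 12 rose and 12 fell, the same adjusted over the list alone, with a median of -0.11, a mean of 0.06 and a test direction up (camera adjusted p = 0.750). That median was -0.21 without control 2, -0.04 without control 3, -0.05 without L-733,060 1, 0.10 without L-733,060 2 and -0.23 without L-733,060 3. The matrix protein Tnc rose from 6.03 ± 1.15 to 112 ± 24.2 CPM and the fibronectin receptor subunit Itga5 by log2 1.59, while Col4a4, which overlaps Col4a3 on the opposite strand, fell by 1.83 and Lamb1 by 1.53 (edgeR adjusted p at most 6.47e-05). Of 20 endothelial genes, 10 rose and 3 fell, also adjusted over the list alone (median 0.64; camera adjusted p = 0.333), with Esam, Flt1, Emcn and Cdh5 higher by log2 2.06, 1.37, 0.87 and 1.26. These endothelial counts were 5 and 3 without control 1, 8 and 1 without control 3, and 11 and 1 without L-733,060 2. Of 12 smooth muscle and pericyte genes, 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (median 1.03, 0.64 without L-733,060 1 and 0.60 without L-733,060 3; camera adjusted p = 0.182, and 0.0301 without L-733,060 2; fry adjusted p = 0.0241). Smooth muscle actin, Acta2, rose from 12.2 ± 1.86 to 145 ± 30.3 CPM, Tagln by log2 1.46 and Actg2 by 2.58 (3.63 without control 1), and Mylk fell by 1.48 (edgeR adjusted p at most 0.00291).

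Several Wnt ligands and the clock output genes fell. Wnt2, Wnt6, Wnt3a and Wnt7b fell by 3.23, 2.94, 2.28 and 1.74 on the log2 scale (edgeR adjusted p at most 1.56e-05). Of 28 tested Wnt and Notch genes, 10 fell and 4 rose, the same adjusted over the list alone; Frzb, a Wnt inhibitor (log2 fold change 3.05, and 3.72 without control 3), and the Notch target Heyl (2.63, 3.30 without control 3 and 1.91 without L-733,060 3) were among those that rose. The list passed camera (median -0.25, and -0.43 without L-733,060 3; adjusted p = 0.0280; adjusted p = 0.469 with an estimated correlation), but not without control 3 (0.0654), without L-733,060 2 (0.0672) or on ranks (0.143). Without control 3 or without L-733,060 1, 3 of its members rose and 6 fell. Of 18 circadian clock genes, 12 fell and 2 rose, likewise adjusted over the list alone (median -0.94; camera adjusted p = 0.00269, adjusted p = 0.288 with an estimated correlation). The clock repressor Nr1d1 fell from 151 ± 14.3 to 29.7 ± 8.57 CPM, and Dbp and Hlf, which the clock drives, fell by 2.14 and 1.51 on the log2 scale, whereas Nfil3 rose by log2 3.12 (edgeR adjusted p at most 6.34e-05). Nr1d1 overlaps Thra, and Dbp overlaps Sphk2, on the opposite strand. Arntl, the clock's activator, measured 8.99 ± 3.56 and 8.59 ± 1.82 CPM (edgeR adjusted p = 0.874). Of 19 immediate early and heat shock genes, which respond to handling and dissection, 4 rose and 7 fell, or 5 and 7 adjusted over the list alone (median 0.09, mean -0.16, test direction down; camera adjusted p = 0.501, fry adjusted p = 0.0412). That median was 0.14, 0.01 and 0.02 without controls 1, 2 and 3, and 0.03, -0.02 and 0.14 without L-733,060 samples 1, 2 and 3. Fos fell by 1.57, Zfp36 by 0.58 and Hspa1a, near-identical to Hspa1b, by 1.58 on the log2 scale, and Hspa8 rose by 0.90 (edgeR adjusted p at most 0.00144).

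Markers of neighbouring tissues were checked beside these groups. Of 9 tested genes of sebaceous, meibomian and Harderian glands, 4 rose and none fell, also adjusted over the list alone (median 0.48; camera adjusted p = 0.00269, adjusted p = 0.213 with an estimated correlation; on ranks 0.149). Lactoferrin, Ltf, a protein of tears and of neutrophil granules, rose from 41.4 ± 6.22 to 4760.0 ± 1279 CPM (log2 fold change 6.85, SE 0.25, edgeR adjusted p = 1.65e-08), Soat1 by log2 2.33, Acsbg1 by 2.06 and Far2 by 0.48. Without L-733,060 3, 1 gland gene fell, and Far2 did not pass without control 1, control 3 or L-733,060 1 (adjusted p = 0.0795, 0.127 and 0.0997). Among lacrimal acinar genes, checked after values were seen, only Amy1 was tested, and it fell by 1.37 on the log2 scale (edgeR adjusted p = 0.0121). The others measured at most 0.339 CPM in either group (Lpo with L-733,060). Of 6 red blood cell genes, 4 rose and 2 fell, also adjusted over the list alone (median 1.45; camera adjusted p = 0.137, fry adjusted p = 0.00562). Hbb-bs, Hba-a1 and Hbb-bt, which share sequence with their duplicates, rose by log2 2.42, 1.77 and 3.26, and Alas2 fell by 1.01 (edgeR adjusted p at most 0.00373). Leaving out any 1 library left 1 red cell gene that fell. Of 6 skeletal muscle genes, 4 fell and none rose, also adjusted over the list alone (median -1.27; camera adjusted p = 0.243, fry adjusted p = 0.00738), at low levels. They were Tnni2, Actn2, Atp2a1 and Ryr1, and 2 fell without control 1, control 2, L-733,060 1 or L-733,060 2. Atp2a1 lost its call in each of those 4 fits (adjusted p 0.0566 to 0.121) and Ryr1 in each fit without 1 library except that without L-733,060 3 (0.0549 to 0.160).

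Lists of the eye's inner tissues were not called by camera, though the melanocyte, iris and ciliary list passed fry (adjusted p = 0.0412). Of 14 retina genes none passed in edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05; 0 by DESeq2 and 1 by limma-voom; median -0.79, camera adjusted p = 0.333), but 7 fell without L-733,060 3. The retina median was 0.13 without control 3, -0.44 without L-733,060 1, -0.40 without L-733,060 2 and -1.58 without L-733,060 3. Of 18 lens genes, 1 rose and none fell, or none adjusted over the list alone (median -0.35; camera adjusted p = 0.978). Lens counts higher and lower were 0 and 0 without control 1, control 2 or L-733,060 1, 2 and 0 without control 3 or L-733,060 2, and 1 and 2 without L-733,060 3. The lens median was -0.65, -0.79 and 1.06 without controls 1, 2 and 3, and -0.23, 0.07 and -1.19 without L-733,060 samples 1, 2 and 3. Of 10 melanocyte, iris and ciliary genes, 4 fell and 1 rose, also adjusted over the list alone (median -0.60, and -0.29 without control 3; camera adjusted p = 0.273). Myoc, a gene of the trabecular meshwork and stroma, fell by 2.70 on the log2 scale, and the melanocyte genes Trpm1, Pmel and Dct fell by 0.88, 0.72 and 1.24. Their counts higher and lower were 0 and 3 without control 1 or L-733,060 1, 0 and 2 without L-733,060 2, and 2 and 5 without L-733,060 3. Pmel lost its call in those first 3 fits (adjusted p 0.0580 to 0.0736), and Dct without control 3 (0.143, with a log2 fold change of -0.76) or L-733,060 2 (0.0729). Of 15 adipocyte genes 4 were tested, too few for a list test. Cidea and Fabp4 rose by log2 2.82 and 3.68, and Lipe and Adrb3 fell by 1.03 and 1.39 (edgeR adjusted p at most 0.00951), and these 2 and 2 were also the counts adjusted over the list alone. Of the 4 tested sex-linked genes, all on the Y chromosome, Ddx3y and Uty rose by log2 0.48 and 0.53 (edgeR adjusted p = 0.0251 and 0.0229; 2 also adjusted over the list alone), which was lost without control 1, control 3, L-733,060 1 or L-733,060 2. The mitochondrially encoded genes were not analysed here.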

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

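All alternatives were chosen before the data were examined. Requiring an absolute log2 fold change of at least 1 left 1684 genes higher and 1305 lower, since that threshold removes smaller changes. Without each sample in turn, 2677 to 3722 genes were higher and 2354 to 3788 lower, and 12 to 13 gene lists passed. With the replicate block, 3609 were higher and 3462 lower, and 12 lists passed; equal numbers correlated at -0.0224, 0.273 and 0.133 across groups, control 1 best with L-733,060 3 (0.163). With the block, 0 retina genes rose and 4 fell, 5 interferon genes rose and 5 fell, and 2 lens genes rose and 1 fell. Mtor passed with the block (adjusted p = 0.0228) and with 4 other alternatives (range over alternatives 0.0121 to 0.302). The other settings stayed within 1.5 times the counts of 3367 and 3129, from 3138 (stricter filter) to 3971 (adjusted p under 0.1) higher and from 2681 (log2 TPM with a pseudocount of 1) to 3773 (quality weights, and adjusted p under 0.1) lower. The median over all genes moved between -0.0155 and 0.0308. Of 28 lists, 0 passed camera with an estimated correlation (5 at an unadjusted p under 0.05), 21 passed fry and 9 passed camera on ranks. Fry, unlike camera, does not compare a list with the other genes. For the conjunctival, lymphocyte and gland lists the estimated correlation (-0.063, -0.030 and 0.0048) lay below the preset 0.01. Their unadjusted camera p still rose, from 0.00243, 0.00364 and 5.88e-04 to 0.0317, 0.0380 and 0.0248. Correlation between members therefore does not account for the loss of these calls. The other called lists had estimated correlations above the preset. The cause of the remaining differences was not tested. Of 2534 comparisons of a named gene with an alternative, 2491 kept the side of the threshold, 33 lost the call, 10 gained it and 0 reversed. In 11 of the 2491, over 3 genes, the sign differed with neither fit past the threshold. For single lists, of 308 comparisons, 277 kept the side of the threshold, 17 lost and 14 gained the call, and 0 reversed. A list past the threshold in neither fit was counted as kept whatever its direction. Depth limits genes near 3 counts, such as Tac1.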

Other observations

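The gene families and the tests of the 3 patterns below were chosen after the result was seen, whereas the splits of the samples were planned. Camera p-values of the families were adjusted over these 8 families only, not together with the 28 planned lists. As the families were picked from the same values, their p-values describe them and are no independent support. Among the families, 19 of 24 tested chemokine ligands rose and 1 fell (median log2 fold change 3.24; camera adjusted p = 4.27e-16, adjusted p = 0.0268 with an estimated correlation). Without control 1 or L-733,060 2, 2 fell. Cxcl17 rose from 0.121 ± 0.142 to 24.5 ± 4.84 CPM and Ccl6 from 6.34 ± 0.739 to 112 ± 12.4 CPM (mean ± SD, n = 3; edgeR adjusted p = 1.64e-07 and 1.65e-08), and Cx3cl1 fell by 1.04 on the log2 scale (edgeR adjusted p = 0.00788). Of 15 matrix metalloproteinases, 11 rose and 1, Mmp28, fell (median 1.47; camera adjusted p = 3.29e-07, adjusted p = 0.0268 with an estimated correlation), and without L-733,060 3, 2 fell. All 8 tested small proline-rich protein genes rose (camera adjusted p = 2.47e-10, adjusted p = 0.0867 with an estimated correlation). Of 30 keratins, 17 rose and 7 fell (median 0.72; camera adjusted p = 0.00471, adjusted p = 0.204 with an estimated correlation).

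Of 18 glycolysis genes, 14 rose and 1, Pfkm, fell (median 1.18; camera adjusted p = 4.10e-09, adjusted p = 0.166 with an estimated correlation), with Gapdh, Eno1, Pkm and Ldha higher by log2 1.26, 1.40, 1.19 and 1.07 (edgeR adjusted p at most 1.58e-04). The 82 cytosolic ribosomal protein genes had a median of -0.01 (-0.10, 0.07 and -0.05 without controls 1, 2 and 3, and -0.06, -0.02 and 0.03 without L-733,060 samples 1, 2 and 3; 1 higher, 2 lower; camera adjusted p = 0.574). In this family 1 was lower without control 2, control 3, L-733,060 1 or L-733,060 2, and 4 were higher without L-733,060 3. The 73 nuclear genes of oxidative phosphorylation had a median of 0.06 (0.19 without control 2, 0.00 without L-733,060 1, 0.12 without L-733,060 2 and 0.11 without L-733,060 3; 10 higher, 3 lower; camera adjusted p = 0.574). Of these, 5 were higher without control 1, 3 without control 3 or L-733,060 1, 6 without L-733,060 2 (with 1 lower) and 17 without L-733,060 3 (with 5 lower). The 21 genes of cholesterol synthesis had a median of -0.06 (0.01, -0.01 and -0.13 without controls 1, 2 and 3, and 0.03, -0.17 and -0.04 without L-733,060 samples 1, 2 and 3; 6 higher, 8 lower; camera adjusted p = 0.467), with 3 higher without control 1 or L-733,060 2 and 2 higher without control 3. The transcription factor gene Sox2 rose from 0.105 ± 0.0502 to 11.7 ± 3.73 CPM (edgeR adjusted p = 3.40e-07). Lens genes varied between samples within both groups, with a mean log2 CPM of 2.09, 0.813 and 3.86 in controls 1 to 3 and 2.46, 1.07 and 3.36 in L-733,060 samples 1 to 3.

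The 6 samples can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3367 genes higher and 3129 lower, and 1 of the 10 splits, the real one, gave as many in each direction. The other 9 splits gave 0 genes by edgeR, with 47 to 1371 genes at an unadjusted p under 0.05 against 7771 in the real split, and 0 to 37 by DESeq2 against 6474. For gene lists, 4 of the 10 splits gave at least the 12 of the real one, and the highest other gave 13. Each of the other splits mixes both treatments on each side. The difference between treatments then adds to the spread within a side, which by design leaves few gene calls. Part of that difference also remains between the sides. Neither the gene counts nor the list counts of these splits therefore show what chance alone would give.

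Of the corneal differentiation genes 10 of 20 fell and 5 rose, while 11 of 15 conjunctival genes rose and 3 fell and 15 of 18 wound and stress genes rose (list calls lost with an estimated correlation, adjusted p = 0.213 each). A lower share of corneal epithelium and nothing else would raise the markers of all other cell types alike. Instead the conjunctival list rose more than the keratocyte list by 1.31 (SE 0.227) on the log2 scale, and the macrophage list more than the Schwann cell list by 1.43 (SE 0.175), which argues against that narrow case. The pairs were picked after the list changes were seen. Keratocytes also lie in the cornea, so a lower share of the whole cornea was not tested. Of the 24 keratocyte list members, 11 rose and 8 fell, so the list mean combines opposite changes. The falls include Kera, Dcn, Lum and Angptl7, and a lower share of the whole cornea stays open. More conjunctival tissue in the antagonist pieces may contribute and cannot be told apart from a change within the epithelium, since 3 members of the conjunctival list fell and corneal epithelium also expresses some of its members. A biological effect of the antagonist stays open as a hypothesis.

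Ppbp and 18 of 19 genes of neutrophils and acute inflammation rose (adjusted p = 0.288 for the list with an estimated correlation). For Ppbp, platelets in the tissue would bring Pf4 at a similar level, but Ppbp exceeded Pf4 185.2-fold (SD 70.5; 142.9 to 266.6 in single L-733,060 samples), which argues against platelets as the main source. Blood in the tissue would bring far more haemoglobin than S100a8 and S100a9 RNA, but the gain in CPM of 4 haemoglobin genes was 0.125 of the gain of S100a8 and S100a9 (0.0523 to 0.531 in single samples), which argues against blood as their main source. Infiltrating leukocytes or expression by the epithelium, as a response to the antagonist or to injection, could remain as hypotheses and were not tested.

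Of the clock genes 12 of 18 fell and 2 rose (adjusted p = 0.288 for the list with an estimated correlation). A different time of day at collection may underlie this and cannot be told apart from an effect of treatment, since the labels give no collection time. Arntl, Clock, Npas2 and Cry1 were grouped as the clock's activator side, although Cry1 is a repressor. Their mean changed by 0.25 (SE 0.124) on the log2 scale beside a change of -1.32 (SE 0.154) in the outputs. Nfil3, a further gene of this group and also a repressor, was left out of that mean after its value was seen. With Nfil3 the change was 0.80 (SE 0.125). A rise of the group of over 0.5 of the output fall by 2 SE would have spoken for the time of day and a fall against it. Neither score met either bound.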
